A study of Homo sapiens with 6 samples.

How the data were processed

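Total RNA of RPMI 8226 cells had been extracted on columns and treated with DNase, and libraries had been made with the NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited 1 table per library with the TPM of each Ensembl transcript, its length-corrected share of the library, per the file headers, and each library summed to 1000000. The submitters' processing notes name STAR, DESeq and the build hg19, with no version and no role, and the tool that made the TPM and its annotation release are not given in the sources used here. TPM are shares of a library, so a rise of some transcripts lowers the others, and they keep no depth, so the precision of low values is unknown.

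Transcript identifiers were matched to GENCODE 29 without their version numbers. Of 173259 transcripts, 159239 (91.9%) matched and belonged to 34500 genes, and 14020 did not match and were left out of the comparisons. The matched transcripts held 97.3% ± 0.005 of the TPM with shLuc and 96.9% ± 0.02 with shHDAC1 (SD, n = 3). Values of a gene's transcripts were summed. Few long noncoding RNAs matched, and the 8 genes of a list meant to follow RNA quality, of short-lived and nuclear-retained RNAs, had 0 matches, so that list could not be used. Coordinates are those of GENCODE 29 on GRCh38, and no position was converted between builds. Genes annotated on chromosome Y were not named.

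Groups followed the sample titles, with 3 shLuc and 3 shHDAC1 libraries. The series describes transductions in triplicate, and p-values measure the spread between these libraries. The test was limma 3.58.1 in R 4.3.3 with a trend in the variance, on log2(TPM + 1), over genes at 1 TPM or more in at least 3 libraries, with Benjamini-Hochberg adjustment over all genes tested and the group as the term. A fold change is on the scale of log2(TPM + 1), which understates the change of low genes. A gene was called at an adjusted p below 0.05. The design had foreseen a count test if the files held counts, and limma if they held TPM.

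Before the data were examined, 35 gene lists with 892 memberships were fixed, of which 884 matched. Lists with at least 5 tested members, 29 in number, were compared with the other genes by camera with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 29 lists. The rotation test fry asked whether a list's genes moved on balance one way. Members called were also counted with the adjustment made over the list alone. The lists without a test were the class I deacetylases, MHC class II, the myeloid, T and NK cell and fibroblast markers, and the RNA quality list.

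Named genes came from a rule fixed before the data were examined. It took HDAC1, HDAC2, HDAC3, HDAC8, IRF4, MYC, PRDM1, XBP1 and CDKN1A, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 TPM whose groups did not overlap, and for each list up to 2 members called in each direction with the smallest p. Members of a list named beyond these (IRF1, SQLE, HSP90B1, CD38, ITGB7 as a plasma cell gene, NFKBIA and H1F0) were chosen after their values were seen, as were all genes and families in the closing observations that are not named before. Genes with near-identical copies or overlapping annotation are reported as uncertain. Some genes are not reported here.

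The alternatives were median centring, quantile normalization, no filter, a mean of at least 5 TPM, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, and the other list tests. Chosen after seeing the data were sums over protein-coding transcripts only, rescaling without histone, immunoglobulin and mitochondrial genes, and a test without genes that hold either of 2 sequences in their 3' UTR. The gene test was tested on simulated data made from these libraries, with 10 sets of 11857 genes of which 200 were changed. It recovered 46.4% of genes changed by 1.5-fold, 74.8% by 2-fold and 93.6% by 4-fold, and 3.93% of its calls were false. The simulated changes were few and of random direction, and the genes varied independently. These shares therefore do not cover errors from scaling or from many genes that change together. The list test called 100% of planted lists. How often it calls lists without change was not shown, since the simulated genes varied independently, and other splits of the libraries called 8 to 12 of the 29 lists with 0 genes called.

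For the closing section, annotated 3' UTRs of at least 30 nucleotides in 10993 tested genes were searched for each 7-mer. Genes were ranked by log2 fold change after regression on 3' UTR length and base composition, and the 16339 7-mers found in at least 20 genes were scored by a z of the ranks of their genes. The score was compared with 100 permutations of the genes, and in simulated data it placed a planted 7-mer first in 20 of 20 sets. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.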

Results

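RNA was measured in RPMI 8226, an established human multiple myeloma line that makes immunoglobulin, after lentiviral delivery of a short hairpin RNA. The control hairpin, shLuc, was directed at luciferase, a gene that human cells lack, and shHDAC1 was directed at HDAC1, a class I histone deacetylase. Each group held 3 libraries, from transductions described as made in triplicate, and the transduced cells had been kept in puromycin for 48 h in medium with 10% serum. Each library listed 173259 transcripts with a TPM value, and the values of each library summed to 1000000. TPM keeps no record of the number of reads, so the depth of the libraries is unknown and no counting error could be given. The libraries held 11654 ± 30.4 genes at 1 TPM or more with shLuc and 11904 ± 79.6 with shHDAC1 (SD, n = 3). Across genes, the correlation of log2 values lay between 0.989 and 0.993 within groups and between 0.971 and 0.974 between groups, and the first principal component, with 64.8% of the variance, separated the groups.

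The first question was how far the hairpin lowered its target. HDAC1 (ENSG00000116478.11, chromosome 1, 32292086 to 32333635, GRCh38) stood at 90.0, 85.0 and 88.9 TPM in the shLuc libraries and at 31.8, 27.0 and 29.2 TPM in the shHDAC1 libraries. The mean fell from 87.9 ± 2.63 to 29.3 ± 2.40 TPM (SD, n = 3), which left 33.3% of the control level. The log2 fold change was -1.56 ± 0.08 (SE; adjusted p = 2.2e-06, limma). The most abundant protein-coding HDAC1 transcript went from 70.7 ± 1.65 to 22.0 ± 1.11 TPM. None of the other class I deacetylases passed the test. HDAC2, the closest relative of HDAC1 and its partner in the same complexes, had a log2 fold change of -0.12 ± 0.07 (adjusted p = 0.27), and its sign turned when only protein-coding transcripts were summed (0.01). HDAC8 had one of -0.12 ± 0.10 (adjusted p = 0.40). HDAC3, the deacetylase of the NCoR and SMRT complexes, had one of 0.29 ± 0.11 (adjusted p = 0.068), and it passed when shLuc replicate 2 was left out (0.40, adjusted p = 0.022).

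**Figure D1:**
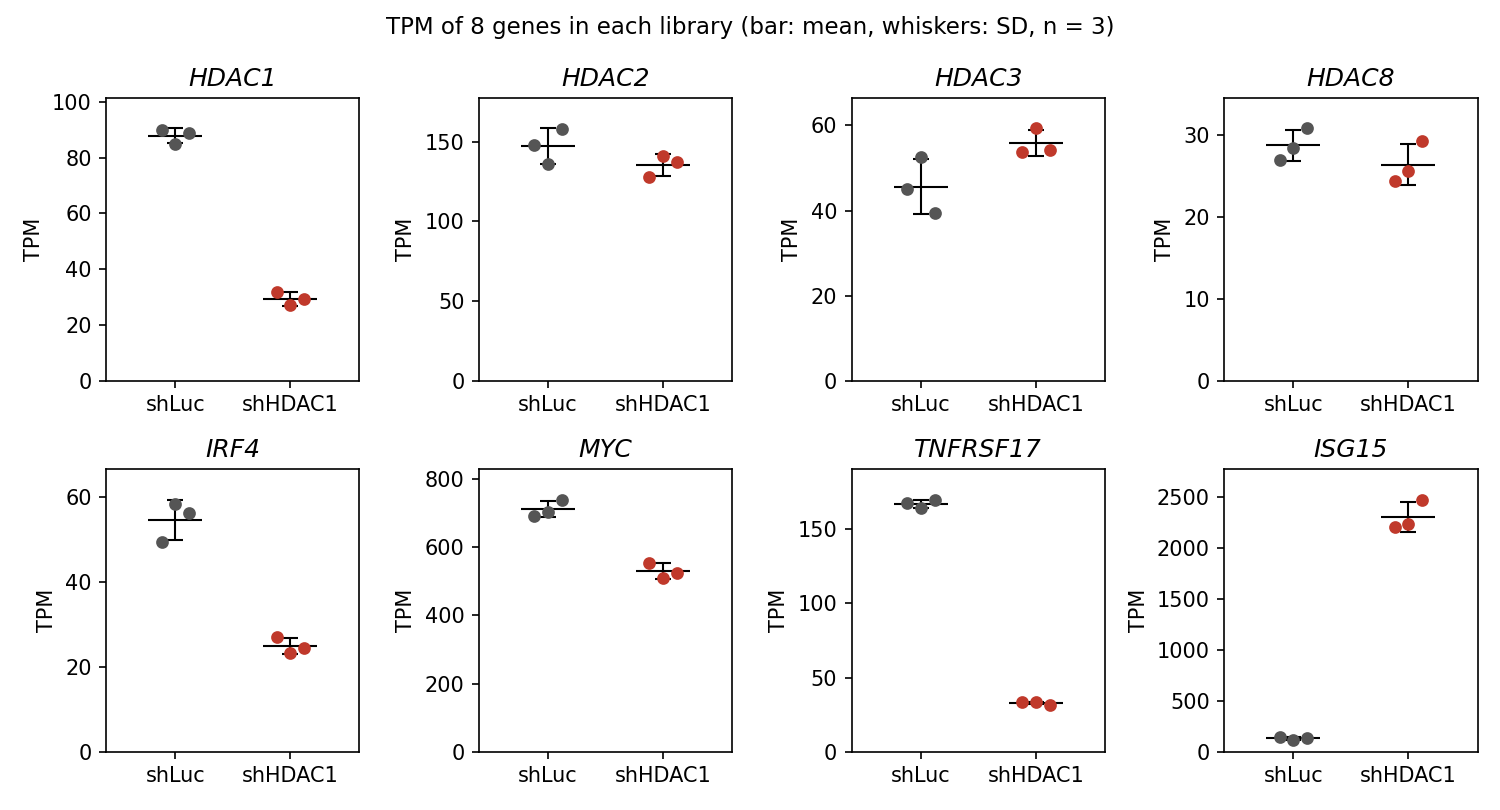
TPM of 8 genes (vertical axes, each starting at 0) in the shLuc libraries (grey points) and the shHDAC1 libraries (red points), with the mean as a horizontal bar and the SD as whiskers (n = 3). HDAC1, IRF4, MYC and TNFRSF17 lie lower in every shHDAC1 library than in any shLuc library, ISG15 lies higher, and HDAC2 and HDAC8 overlap between the groups.

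Of 11857 genes tested, 3226 differed between the groups at an adjusted p below 0.05 (limma), of which 2007 were higher and 1219 were lower with shHDAC1. Among these, 255 were higher and 86 were lower by at least 2-fold, counts that depended on the scaling (133 lower after median centring, 135 after quantile normalization) and the pseudocount (383 higher and 136 lower with 0.1, 133 and 45 with 5). The groups did not overlap for 43.3% of all genes tested, against the 10% that chance gives for 3 libraries against 3. The balance between the directions depended on the scaling. Higher genes made up 62.2% of the calls on TPM as deposited, 42.2% after each library was centred on its median (1336 higher, 1828 lower) and 47.0% after quantile normalization (1412 higher, 1591 lower). The count of higher genes was 1303 without shLuc replicate 1 and 1295 without shHDAC1 replicate 1.

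**Figure D2:**
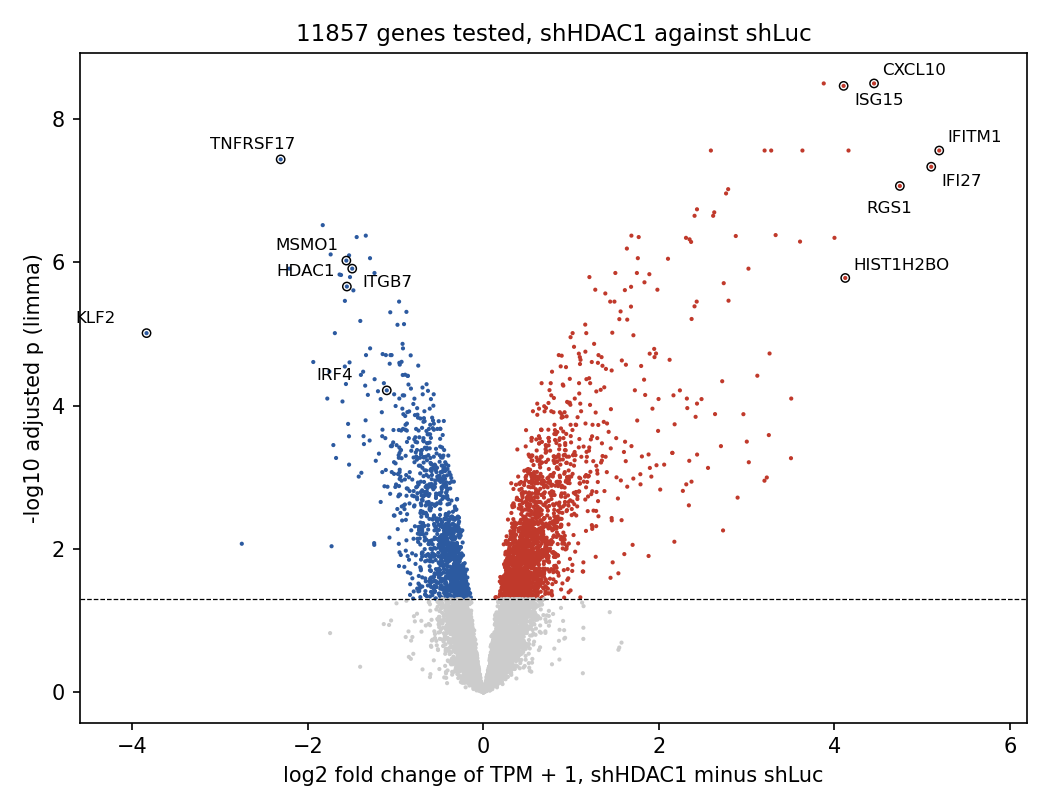
Log2 fold change of TPM + 1 (horizontal axis, shHDAC1 minus shLuc) against the negative log10 of the limma adjusted p (vertical axis) for the 11857 genes tested. Red points are the 2007 genes called higher, blue points the 1219 called lower and grey points the others, and the dashed line marks the threshold of 0.05. CXCL10 and ISG15 lie at the top right and TNFRSF17 at the top left.

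Interferon-stimulated genes, the antiviral program that cells switch on in response to interferons, rose together. Of 39 members tested, 38 were higher and none was lower, with a median log2 fold change of 2.35, and the counts were the same when adjusted over the list alone. The exception was IRF1 (0.17 ± 0.08, adjusted p = 0.16). ISG15, a ubiquitin-like modifier, went from 133 ± 12.2 to 2305 ± 147 TPM, IFI6 from 171 ± 11.7 to 2529 ± 145 TPM and IFI27 from 15.0 ± 2.96 to 549.6 ± 96.6 TPM (SD, n = 3). As a group, these genes were called higher with a preset correlation (camera, adjusted p = 1.6e-38), and the call held with an estimated correlation (adjusted p = 0.038).

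The 12 genes with the largest increases were mostly of the same kind. IFITM1, a membrane protein that restricts virus entry, rose by 5.19 ± 0.13 on the log2 scale, from 2.89 to 141 TPM. CXCL10, a chemokine induced by interferons, rose by 4.45 ± 0.08 and reached 1109 ± 95.4 TPM from 49.7 ± 3.46 TPM. IFI27, IFI44L, ISG15, MX2, IFI6, IFI44 and OAS3, all members of the interferon list, rose by between 3.61 and 5.10. RGS1, a regulator of G protein signalling in B cells, rose by 4.75 ± 0.15, from 1.06 ± 0.35 to 53.8 ± 4.61 TPM. The others were HIST1H2BO (4.12 ± 0.21) and the histone pseudogene HIST2H2BB (3.51 ± 0.32), whose values are uncertain because histone genes of 1 kind have near-identical copies.

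Genes of plasma cell and myeloma identity fell. Of 27 members tested, 18 were lower and 2 were higher (19 lower and 3 higher when adjusted over the list alone), with a median log2 fold change of -0.34. IRF4 (ENSG00000137265.14, chromosome 6, 391739 to 411447), a transcription factor on which myeloma cells depend, fell from 54.7 ± 4.75 to 24.9 ± 1.92 TPM, a log2 fold change of -1.10 ± 0.09 (adjusted p = 6.1e-05). Its annotated 3' UTR holds the sequence GACAAACA, and of the 235 genes searched that hold it there 34.9% were called lower and 7.66% higher, against 9.24% lower and 18.4% higher of the 9344 genes without GACAAAC anywhere in the transcript. TNFRSF17, which encodes the surface receptor BCMA, fell from 167 ± 2.80 to 32.9 ± 0.96 TPM. The integrin ITGB7 fell from 1909 ± 105 to 677 ± 55.7 TPM and CD38 from 141 ± 5.15 to 88.1 ± 9.41 TPM. TXNDC5, a protein disulfide isomerase whose annotation overlaps a readthrough gene and whose value is therefore uncertain, had a log2 fold change of -1.34 ± 0.05. The plasma cell list was called lower (camera, adjusted p = 2.7e-10), but not with an estimated correlation (adjusted p = 0.078).

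PRDM1 and XBP1, which drive plasma cell differentiation and the secretory program, were lower by less. XBP1 had a log2 fold change of -0.21 ± 0.06 (adjusted p = 0.023), and PRDM1 one of -0.58 ± 0.18 (adjusted p = 0.040). Neither call held throughout. PRDM1 missed the threshold without shLuc replicate 1 (adjusted p = 0.057), 2 (0.13) or 3 (0.078) and without shHDAC1 replicate 1 (0.12) or 2 (0.098). XBP1 missed it without shLuc replicate 1 (0.064) or 2 (0.068) and without shHDAC1 replicate 3 (0.085). Immunoglobulin genes together took 2.59% ± 0.05 of the TPM with shLuc and 1.98% ± 0.04 with shHDAC1 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

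Among the 12 largest decreases, KLF2, a transcription factor of lymphocyte quiescence, went from 39.6 ± 1.93 to 1.99 ± 1.08 TPM (log2 fold change -3.84 ± 0.25). AZGP1, CALU, an ER calcium-binding protein, FUT8, the enzyme that adds core fucose to N-glycans, PLEKHA3, C1QA and C2orf76 had log2 fold changes between -1.83 and -1.69. TNFRSF17 (-2.31 ± 0.06) also belonged to this group. KRT86 (-2.21 ± 0.11) and KRT81 (-1.94 ± 0.14) share long stretches of sequence, and EIF4EP2 (-2.75 ± 0.59) and LSM12P1 (-1.73 ± 0.38) are processed pseudogenes, so their values are uncertain. With HDAC1 left out, 80 genes searched were called lower by at least 2-fold, and 18 of them (22.5%) held GACAAAC in their 3' UTR. Of all genes searched, 5.61% held it there.

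Genes of cholesterol synthesis and other SREBP2 targets fell. Of 24 tested, 16 were lower and none was higher (19 lower when adjusted over the list alone), with a median log2 fold change of -0.42. MSMO1, a sterol-C4 oxidase, fell from 258 ± 15.6 to 86.8 ± 5.22 TPM, INSIG1, a sterol-regulated gene, from 205 ± 4.28 to 86.2 ± 3.26 TPM and SQLE from 126 ± 11.1 to 56.7 ± 5.76 TPM. The cholesterol list was called lower (camera, adjusted p = 6.6e-14), and the call held with an estimated correlation (adjusted p = 0.028).

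Genes of the unfolded protein response and ER chaperones also fell, with 18 of 30 lower and none higher (19 lower when adjusted over the list alone) and a median log2 fold change of -0.33. SSR1, a subunit of the translocon-associated complex, fell from 932 ± 50.0 to 554 ± 48.7 TPM, the chaperone CALR from 1324 ± 46.9 to 940.5 ± 30.2 TPM and HSP90B1 from 796 ± 68.0 to 521 ± 10.7 TPM. The chaperone list was called lower (camera, adjusted p = 3.2e-11), but not with an estimated correlation (adjusted p = 0.078). The ATF4 and amino acid stress list had 11 lower and 5 higher of 27 (12 and 5 when adjusted over the list alone). ATF4 itself (-0.60 ± 0.05) and the amino acid transporter SLC7A5 (-0.86 ± 0.07) were lower, while NUPR1 (1.30 ± 0.19) and ATF3 (0.62 ± 0.10), both stress-induced regulators, were higher. That list was called lower (camera, adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.50).

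MYC fell from 712 ± 24.8 to 529.5 ± 22.9 TPM, a log2 fold change of -0.43 ± 0.06 (adjusted p = 6.5e-04). Of 40 MYC target genes, 19 were lower and 3 were higher, also when adjusted over the list alone, with a median of -0.14. ODC1, the first enzyme of polyamine synthesis, had a log2 fold change of -0.45 ± 0.05 and the nucleolar protein GNL3 one of -0.46 ± 0.06, while the mitochondrial chaperonin subunit HSPE1 rose by 1.09 ± 0.08. Together the targets were called lower (camera, adjusted p = 5.8e-06), but not with an estimated correlation (adjusted p = 0.078).

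The cell cycle lists moved less. Of 40 G1/S and DNA replication genes, 10 were lower and 3 were higher (10 and 4 when adjusted over the list alone), among them UHRF1 (-0.87 ± 0.08) and the licensing factor CDC6 (-0.60 ± 0.08) on the lower side. The G1/S list was called lower (camera, adjusted p = 0.039), but not with an estimated correlation (adjusted p = 0.58), without shLuc replicate 2 (0.054) or without shHDAC1 replicate 3 (0.11). Its call was also lost with a mean of at least 5 TPM (adjusted p = 0.073), protein-coding transcripts only (0.052), rescaling without histone, immunoglobulin and mitochondrial genes (0.053) and without genes that hold GACAAAC or ATCGTCA in their 3' UTR (0.059). Of 39 G2/M and mitosis genes, 5 were higher and 5 were lower (5 and 4 when adjusted over the list alone), with the mitotic kinase AURKB at 0.69 ± 0.06 and cyclin CCNA2 at -0.39 ± 0.07. That list was not called (camera, adjusted p = 0.54), and its median (-0.01) and mean (0.02) differed in sign.

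CDKN1A, which encodes the p53-regulated inhibitor p21, fell from 46.4 ± 3.70 to 27.2 ± 4.38 TPM (-0.76 ± 0.12, adjusted p = 0.0019). Of the 6 CDK inhibitor genes tested, 2 were higher and 1 was lower, also when adjusted over the list alone, and CDKN2A rose by 0.41 ± 0.06. The list was not called (camera, adjusted p = 0.99). Of 23 p53 target genes, 6 were lower and 3 were higher, also when adjusted over the list alone, with BTG2 at -0.79 ± 0.09 and CCNG1 at -0.45 ± 0.06. The p53 list was called lower (camera, adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.58), with protein-coding transcripts only (adjusted p = 0.15) or among genes with a mean of at least 5 TPM (adjusted p = 0.073).

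NF-kB target genes rose, with 14 of 19 higher and none lower (15 higher when adjusted over the list alone) and a median of 0.64. The lymphotoxin gene LTB rose by 1.01 ± 0.11 and the NF-kB inhibitor gene NFKBIA by 0.71 ± 0.08. The NF-kB list was called higher (camera, adjusted p = 2.2e-05), but not with an estimated correlation (adjusted p = 0.11). Genes of MHC class I antigen presentation rose as well, with 10 of 14 higher and none lower (11 higher when adjusted over the list alone) and a median of 0.65. The immunoproteasome subunit PSMB9 rose by 1.04 ± 0.09 and the peptide transporter subunit TAP1 by 0.99 ± 0.10. The values of the HLA genes in the list are uncertain, since transcripts of alternative haplotypes lie among those with no gene in the annotation. This list was called higher (camera, adjusted p = 2.1e-04), but not with an estimated correlation (adjusted p = 0.078).

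Replication-dependent histone genes were higher in 17 of 18 cases, also when adjusted over the list alone, with a median of 2.36. HIST1H2AI went from 0.61 ± 0.50 to 14.2 ± 3.16 TPM and HIST1H3B from 1.21 ± 0.70 to 17.8 ± 4.24 TPM, values that are uncertain because of near-identical copies. H1F0, which encodes a linker histone made outside S phase, had a log2 fold change of 0.04 ± 0.10 (adjusted p = 0.82). The histone list was called higher (camera, adjusted p = 4.3e-11), but not with an estimated correlation (adjusted p = 0.27). Mitochondrially encoded mRNAs were higher in 6 of 11 cases and lower in none (10 higher when adjusted over the list alone), with MT-CO1 at 0.69 ± 0.13 and MT-CO3 at 0.59 ± 0.11. That list was called higher (camera, adjusted p = 0.0060), but not with an estimated correlation (adjusted p = 0.58). The mitochondrial share of the TPM was 1.59% ± 0.08 with shLuc and 2.28% ± 0.51 with shHDAC1 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), with 2.85% in shHDAC1 replicate 1.

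Neuronal genes of the kind that the repressor REST keeps silent were mostly below the level tested, and of 6 tested 4 were lower and none was higher, also when adjusted over the list alone. The tubulin gene TUBB3 fell from 9.87 ± 1.32 to 2.48 ± 0.96 TPM and STMN3 from 2.74 ± 0.32 to 0.68 ± 0.15 TPM. The neuronal list was called lower (camera, adjusted p = 0.0032), but not with an estimated correlation (adjusted p = 0.11) or when only protein-coding transcripts were summed (adjusted p = 0.052). When any shLuc library was left out, too few of its members were tested for a list test. The same held with a mean of at least 5 TPM. Those settings therefore do not show whether the call holds. STMN3, and any other member that passed the filter only through the shLuc libraries, could hardly have come out higher. The counts, the median and the call of this list are therefore partly set by the filter. With no filter on low values the list was still called lower (camera, adjusted p = 0.017).

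The mature B cell program had 8 higher and 3 lower of 16 (9 and 4 when adjusted over the list alone) and was not called (camera, adjusted p = 0.14), though it was called higher with a mean of at least 5 TPM (adjusted p = 0.041), without shLuc replicate 1 (0.037) and with fry (0.011). The transcription factor ETS1 rose by 1.06 ± 0.11 and CD74, the MHC class II invariant chain, by 0.75 ± 0.06, while the IgE receptor FCER2 had a log2 fold change of -1.61 ± 0.15. Of the adhesion and bone marrow homing genes, 5 were higher and 6 lower of 20 (6 and 6 when adjusted over the list alone), with the chemokine receptor CCR1 at 0.48 ± 0.07 and ITGB7 at -1.49 ± 0.07 (camera, adjusted p = 0.25; called lower with fry, adjusted p = 0.047). The immediate early genes had 5 higher and 3 lower of 16 (5 and 5 when adjusted over the list alone), with EGR3 at 1.53 ± 0.25 and KLF2 at the other end (camera, adjusted p = 0.39). The BCL2 family and cell death regulators had 5 higher and 3 lower of 24, also when adjusted over the list alone (camera, adjusted p = 0.81; called higher with fry, adjusted p = 0.021). The mitochondrial death activator DIABLO rose by 0.94 ± 0.07, and the survival gene BCL2L1 had a log2 fold change of -0.68 ± 0.08.

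Subunits of the corepressor complexes that hold HDAC1 had 6 higher and 3 lower of 29 (7 and 3 when adjusted over the list alone; camera, adjusted p = 0.81). The NuRD subunit MBD2 had a log2 fold change of -0.89 ± 0.07 and GATAD2A one of 0.49 ± 0.10. The other deacetylases and sirtuins had 1 higher and 3 lower of 13, also when adjusted over the list alone (camera, adjusted p = 0.81). Autophagy and lysosome genes had 4 higher and 6 lower of 26 (4 and 7 when adjusted over the list alone; camera, adjusted p = 0.25), with the autophagy receptor SQSTM1 at 0.82 ± 0.09 and the protease CTSB at -1.53 ± 0.07. Glycolysis and hypoxia genes had 5 higher and 4 lower of 26 (5 and 5 when adjusted over the list alone; camera, adjusted p = 0.46), with PFKFB3 at 0.84 ± 0.16 and NDRG1 at -1.16 ± 0.11.

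The remaining lists were not called with all 6 libraries on TPM as deposited either. The cytosolic ribosomal proteins had 4 higher and 7 lower of 62, also when adjusted over the list alone (camera, adjusted p = 0.058). That result turned on scaling and single libraries: the list was called lower after median centring (adjusted p = 0.013), without shLuc replicate 2 (0.019) or 3 (0.039) and without shHDAC1 replicate 2 (0.0015) or 3 (0.015), while without shHDAC1 replicate 1 the test pointed up (0.99). Nuclear-encoded oxidative phosphorylation genes had 3 higher and 3 lower of 44, and none in either direction when adjusted over the list alone (camera, adjusted p = 0.39; called lower without shHDAC1 replicate 2, adjusted p = 0.032). The proteasome genes had 2 higher and 2 lower of 31 (1 and 1 when adjusted over the list alone; camera, adjusted p = 0.39). The heat shock proteins had 3 higher and 4 lower of 16, also when adjusted over the list alone (camera, adjusted p = 0.39), and their median (-0.06) and mean (0.03) differed in sign. The homologous recombination and DNA damage checkpoint genes had 2 higher and 1 lower of 30, also when adjusted over the list alone (camera, adjusted p = 0.99). The median, the mean and the direction of the test were not all of 1 sign in the lists of oxidative phosphorylation, proteasome, homologous recombination, autophagy, other deacetylases, epithelial markers and CDK inhibitors either.

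Markers of other cell types were mostly below the level tested. Of 16 myeloid markers 2 were tested, and the integrin ITGAM rose by 1.17 ± 0.16. Of 16 T and NK cell markers 2 were tested and 1 was called higher, and of 14 MHC class II genes 4 were tested, with 1 higher and 1 lower. Of 16 fibroblast and stromal markers 2 were tested and 1, FN1, was called lower (-0.41 ± 0.09). FN1 was an abundant exception, with a mean of 1141 TPM over all libraries. Of 14 epithelial and HEK293-type markers 6 were tested, 1 was higher and none was lower, also when adjusted over the list alone (camera, adjusted p = 0.99). The higher one was the intermediate filament gene VIM (0.51 ± 0.10).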

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

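Transcripts with no gene in the annotation used here, which entered no comparison, took 3.14% ± 0.02 of the TPM with shHDAC1 against 2.72% ± 0.005 with shLuc (SD, n = 3). The share was higher in all 3 shHDAC1 libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). This signal outside the gene comparisons was above the level in the control libraries. The groups of 3 were too small for a search for single outlying libraries.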

How the results depend on the processing

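Sums over protein-coding transcripts, rescaling without histone, immunoglobulin and mitochondrial genes, and leaving out genes with a 3' UTR match were chosen after seeing the data. HDAC1 was called lower in every alternative run that tested it. It holds GACAAAC in its 3' UTR, so the run without genes with a 3' UTR match left it out. Leaving out 1 library gave 1295 to 1981 higher and 867 to 1076 lower genes, with the low counts of higher genes without shHDAC1 replicate 1 (1295) and shLuc replicate 1 (1303). Median centring gave 1336 higher genes and 133 lower by at least 2-fold, and quantile normalization 135 of the latter, since these scalings move the median of all genes from 0.07 to -0.03 and -0.01. At least 2-fold higher and lower were 383 and 136 genes with a pseudocount of 0.1, and 133 and 45 with 5, since the pseudocount sets the fold of low genes. Lists called lower numbered 5 with a mean of at least 5 TPM, where the neuronal list had too few members for a test. They numbered 5 with protein-coding transcripts only, and the cause of the other losses was not tested. Lists called higher numbered 3 in the rescaled data, which hold no histone or mitochondrial list. With an estimated correlation, 1 list was higher and 1 was lower. With fry, the G1/S (adjusted p = 0.13), mitochondrial (0.078) and p53 (0.078) lists missed the threshold, and the mature B cell (higher, 0.011), BCL2 family (higher, 0.021) and adhesion (lower, 0.047) lists passed it.

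Of the named genes' values, 1769 pairs of gene and setting stayed on the same side of the threshold in the same direction, 156 lost the call, 2 gained one and 2 turned in sign. The latter were HDAC2 (0.012, adjusted p = 0.91) and SIRT1 (0.063, adjusted p = 0.75) with protein-coding transcripts only, and the cause was not tested. Deviations of libraries with equal replicate numbers correlated at -0.10, 0.18 and 0.03, and those with unequal numbers at -0.16 to 0.15. These values gave no clear sign that the numbers pair the libraries, but with 3 libraries per group they cannot exclude it. With the replicate block, 1979 genes were higher and 1264 lower, and HDAC1 stood at -1.56. DESeq2, limma-voom and scaling by library totals, planned for counts, were not run, as the files hold TPM. No depth could be given, so what depth limits is unknown.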

Other observations

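All tests in this part were chosen after the results were seen. Of 6 APOBEC3 cytidine deaminase genes tested, 3 were lower and 2 were higher. APOBEC3B fell from 119.9 ± 4.17 to 63.0 ± 0.95 TPM and APOBEC3F from 81.7 ± 5.20 to 44.0 ± 6.96 TPM, while APOBEC3A went from 0.59 ± 0.15 to 2.06 ± 0.30 TPM, an uncertain value as its annotation overlaps that of APOBEC3B. Of 9 keratin genes, 5 were lower and none was higher, with KRT7 at -0.76 ± 0.10. REST rose from 3.79 ± 0.98 to 9.17 ± 0.43 TPM, beside the lower neuronal list. All 7 MTRNR2L genes tested, nuclear copies of the mitochondrial 16S ribosomal RNA whose reads cannot be told from it, were higher, with a median of 1.79.

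Genes with GACAAAC in their 3' UTR were lower with shHDAC1: the 617 such genes had a median log2 fold change of -0.08 and 25.9% were called lower, against 0.08 and 9.24% for the 9344 genes without it anywhere in the transcript and 0.02 for the 1032 with it only outside the 3' UTR, of which 165 were called lower. The score of this 7-mer, -11.75, lay outside the lowest of 104 7-mers of the same bases (-2.73) and the lowest of 100 permutations (-5.01), which argues against 3' UTR length, 3' UTR base composition and chance among 7-mers. The length and composition of the rest of the transcript were not in the regression. A candidate explanation is pairing of the HDAC1 hairpin's seed, since the 7-mer lies in the HDAC1 transcript (chromosome 1, 32333316 to 32333322 in the 3' UTR, GRCh38), as do 11.9% of all 7-mers, and the 235 genes where A follows (GACAAACA, median -0.19) were lower than the other matches (-0.01, one-sided permutation p = 2.0e-05). The 3' UTR of IRF4 holds GACAAACA (its first 7 bases at chromosome 6, 409307 to 409313). Of the 235 genes with GACAAACA there, 15 were called lower by at least 2-fold. The same held for 3 of the 382 other matches and 56 of the 9344 genes without GACAAAC. Of all 617 matches, 14, IRF4 included, fell at least as far as IRF4. Whether the fall of IRF4 came through the seed, through lower HDAC1 or both cannot be told apart. All shHDAC1 libraries had lower HDAC1, and 1 knockdown group was made. Of the lists called lower, the 7-mer was held by 0 of 24 cholesterol, 0 of 40 MYC target, 0 of 6 neuronal, 1 of 26 plasma cell (IRF4), 2 of 30 ER chaperone (ERO1B, SPCS3), 2 of 27 ATF4 (TRIB3, SLC7A5), 1 of 40 G1/S (UHRF1) and 1 of 23 p53 genes searched (ZMAT3). Without genes holding GACAAAC or ATCGTCA only the G1/S call was lost (camera, adjusted p = 0.059). These values cover direct pairing with a list's own genes only. Whether the lists fell in consequence of a lower carrier such as IRF4 was not tested.

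Interferon-stimulated genes had a median log2 fold change of 2.25 after each library was centred on its median, which argues against an effect of scaling. Genes with ATCGTCA in their 3' UTR were higher with shHDAC1 (score 8.11, 127 genes, 44.9% called higher), which might come from the control hairpin's seed, but none of the 39 interferon genes held it and their median was 2.35. IFNB1, an interferon gene, rose from 0.41 ± 0.31 to 1.85 ± 0.44 TPM, by 1.03 ± 0.21 on the log2 scale (limma, adjusted p = 0.0064). A response to the hairpin and a response to lower HDAC1 cannot be told apart, since 1 knockdown group stands against 1 control group.

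Histone genes named HIST summed to 169 ± 66.8 TPM with shLuc and 1104 ± 296 TPM with shHDAC1 (SD, n = 3), and 44 of 47 tested were called higher. More cells in S phase would raise the G1/S list, whose median was -0.041 with 10 of 40 lower and 3 higher. Other protein-coding genes no longer than the median histone gene, 585 nucleotides, had a median of -0.022 over 121 genes, against a gain of short transcripts (a first version with a bound of 2194 nucleotides gave 0.05). The 8 histone genes taken as replication-independent, H2AFX among them, whose mRNAs mostly carry a poly(A) tail, had a median of 0.016 (-0.30 to 0.66). More RNA without a poly(A) tail in the shHDAC1 libraries may give this, and so may a change in the histone mRNAs themselves, and these cannot be told apart. The 7 MTRNR2L genes (median 1.79) were higher too, but so were mitochondrial mRNAs, which carry a poly(A) tail (6 of 11 higher, median 0.46), and a further test, on a gene of chromosome Y that was also higher, is left out of this weighing and its value is not reported.

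The 6 libraries make 10 splits into 3 and 3, too few for a share below 0.05. The real split gave 2007 higher and 1219 lower genes and 341 genes changed by at least 2-fold, and the highest of the other splits gave 0 in each (limma, with 131 to 643 genes at an unadjusted p below 0.05). Every other split mixes the groups, so their difference enters the spread and calls become rare. The lack of calls there therefore does not show how many calls chance would give. For called lists the real split gave 13 and the other splits 8 to 12, though each of these still sets 2 libraries of a group against 1. In each case 1 of the 10 splits, the real one, gave a result as large.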
